A study of Homo sapiens with 6 samples.

How the data were processed

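The series covers 6 samples of islet organoids derived from the human embryonic stem cell line MEL1, which carries reporters at INS and NKX6-1. Per the labels, 4 are an scRNA-seq cDNA library and an scATAC-seq library of each group, DMSO and SU6656. The other 2 are oligo libraries of the scRNA-seq runs, which were not analysed here. Each group thus has 1 library per assay. The dose and duration of SU6656 are not given in the sources used here.

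The authors deposited scRNA-seq values as raw UMI counts per gene symbol and barcode. Per the labels, the libraries were made with the DNBelab C kit, in which read 1 carries the cell barcodes and the UMI, and per the file headers the matrices were written by PISA 1.0. The genome build was GRCh38, per the submitters' processing notes. The aligner, the annotation, the use of strand and the way barcodes were called are not given in the sources used here. In the files every barcode has at least 1000 UMIs and only genes with a UMI in that library are listed. The deposited scATAC-seq values are raw counts per peak and barcode. Per the file headers they come from cellranger-atac 2.1.0, whereas the submitters' processing notes name Cell Ranger ATAC 1.1.0. The peak lists of the libraries differ, so peaks were called per library. Of the scATAC-seq values 91.9% in DMSO and 91.1% in SU6656 are even, as when both ends of a fragment are counted, so intervals were computed on the counts divided by 2.

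RNA cells were kept with at least 500 genes and at most 20% mitochondrial UMIs. This left out 16 DMSO and 6 SU6656 barcodes with too few genes and 56 and 64 with too many mitochondrial UMIs. The median mitochondrial share was 0.392% and 0.376%. Scrublet, run per library in scanpy 1.11.5, marked 0 cells at its thresholds of 0.595 and 0.631. A caller that marks none of so many cells has not worked, so doublets were kept and stay possible in every class. Cells of both libraries were normalised to 10000 UMIs, and clustered on 2000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9, seed 0) without integration, which gave 16 clusters. Markers of 17 classes, fixed before the data were examined with the gene lists, the comparisons and most alternatives, named the clusters.

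The scoring of those markers was set after the data were seen. A marker counted as raised at 1.5-fold or more over the other cells and at least 20 CPM. A name needed at least 3 raised markers and more than any other class. A cluster stayed unnamed with MALAT1 at 10000 CPM or more, with 3 or more low-quality markers raised, with a hormone at 20000 CPM or more under a class without hormones, or with more markers of another class among its top 10 genes by fold, computed with 10 CPM added. The last check decided the beta-like set, because with 1 CPM added clusters 1 and 7 were both beta-like and with 10 CPM cluster 7 alone was. A pool of the INS-high clusters 1, 3 and 7 was also analysed as a beta cell set before cluster 7 was taken, as the design fixed the beta-like class. The sets differ in results: the metallothionein list lies at percentile 6.74 in cluster 7, 10.5 in clusters 1 and 7, 19.0 in cluster 1, and 0 in cluster 3 and in the pool. All are given as alternatives.

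Counts were summed per library and set of cells and divided by the set's total to give CPM. The ratio SU6656 over DMSO carries an exact conditional binomial 95% interval, and class shares carry exact (Clopper-Pearson) binomial intervals, with Newcombe's interval for their difference in points. These cover counting error only and no test or p-value was used, since cells are not replicates. A gene was measured with at least 50 UMIs over both libraries, and called higher or lower at 1.5-fold or more with an interval that excludes 1. No ratio is given against a count of 0 (a count of 0 in all kept cells allows up to 0.0521 CPM in DMSO and 0.0608 CPM in SU6656, at 3 counts).

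The 19 gene lists covered beta cell genes, zinc transporters, metallothioneins, hypoxia genes, pro-angiogenic factors, glycolysis, mitochondrially and nuclear encoded respiratory chain, ATF4 and CHOP targets, endoplasmic reticulum chaperones, heat shock, immediate early genes, YAP and SRF targets, Src kinases, mitosis, p53 targets, oxidative stress, cholesterol synthesis and extracellular matrix. Of their 463 genes, 462 were found among the RNA symbols. Each list's median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, a description of these libraries. A list counts as outside when below the 2.5th or above the 97.5th percentile.

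Genes were named by a fixed rule. In beta-like cells it takes the 12 largest and 12 smallest ratios among genes with at least 100 UMIs, an interval that excludes 1, and at least 1.2-fold in the same direction after each cell was thinned to 1500 UMIs. Of the largest, 2 are clone names and were counted but not named, and some items the rule takes are not reported here. Of each list it takes up to 4 members with the largest ratios either way, and 14 genes are always named. For gene ends it takes the 5 largest and 5 smallest of protein-coding genes with at least 500 counts. Genes of other cell sets named in the text were chosen after their values were seen. Thinning kept 7041 DMSO and 8900 SU6656 cells, of which 323 and 260 were beta-like. Thinned ratios rest on fewer counts and are given without an interval. Genes read out for the sex of a donor or line were left out of all tables.

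For ATAC, overlapping peaks of both libraries were merged into 276463 regions, of which 219069 had a peak in both. Ratios were scaled by the counts in those regions, with at least 100 counts per region. The gene table used here (GRCh38) gives no strand, so the planned promoter regions were replaced by regions within 1 kb of either annotated gene end. Of 32200 RNA symbols 21407 (66.5%) matched that table. No genome sequence was used here, so the planned search for DNA motifs was left out. ATAC classes came from barcodes with at least 1000 counts, 50000 regions, 30 singular vectors without the first and Leiden at 0.5, named from accessibility over the gene body and 2 kb around it.

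Scripts were tested on simulated data with 200 features of known fold, 50 at each of 4 sizes. Summed counts were drawn with counting error only, so the rates below leave out variation between cells and between cultures. For all cells, 48 of 50 2-fold, 50 of 50 3-fold, 49 of 50 0.5-fold and 50 of 50 0.333-fold genes were recovered, and 139 of 19337 genes measured (0.726% of the unchanged) were called without a difference. In beta-like cells 50, 50, 48 and 50 of 50 were recovered and 165 of 9224 (1.83%) were called without a difference. For ATAC, simulated on the DMSO peaks and not on merged regions, 49, 50, 47 and 46 of 50 were recovered, and 2652 of 250528 (1.06%) were called without a difference. Of 200 random lists of 25 unchanged genes 12 lay outside the percentile limits, and 20 of 20 lists moved 1.3-fold lay above the 97.5th percentile.

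For genes that moved alike in all large clusters, a search for neighbours had to cover 0.8 of the genes to decide for the whole set, a limit set after its value was seen.

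Alternatives covered scaling by the median ratio, the mean of each cell's CPM, other filters on cells and counts, a 2-fold rule, thinning to 1 depth, other clustering, other sets of INS-expressing cells, other overlap rules and other barcode minimums. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 was used.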

Results

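Islet organoids were grown from human embryonic stem cells, and the series labels name a vehicle group (DMSO) and a group given SU6656, an inhibitor of Src family kinases. The series title places the comparison in the study of zinc transport, hypoxia and vessel growth, so zinc handling, hypoxia and angiogenic genes were among the gene lists fixed in advance. Single-cell RNA sequencing (scRNA-seq, droplet libraries with unique molecular identifiers, UMIs) and single-cell ATAC sequencing (scATAC-seq, which counts transposase insertions in open chromatin) each had 1 library per group. The DMSO scRNA-seq matrix held 7947 barcodes with 57744641 UMIs, a median of 5110 UMIs and 2304 genes per barcode. The SU6656 matrix held 10047 barcodes with 49432506 UMIs, a median of 3798 UMIs and 1821 genes. After filtering, 7891 DMSO and 9982 SU6656 cells were kept. The scATAC-seq matrices held 14244 DMSO barcodes with 211532119 counts and 13750 SU6656 barcodes with 197105127 counts. With 1 library per group there is no replicate check on any difference given here. Intervals are 95% intervals that cover counting error only, and a gene or region is called higher or lower when its ratio, SU6656 over DMSO, of counts scaled to 1000000 per library (CPM) is at least 1.5-fold and the interval excludes 1.

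The organoids held the main endocrine types of the islet together with enterochromaffin-like cells, the serotonin-producing cells that arise in such cultures. A class named beta-like by its raised markers, among them INS, IAPP, PCSK1 and G6PC2, although neuronal genes such as NEFL and NEFM led its genes by fold, made up 4.35% of DMSO cells (exact binomial interval 3.91 to 4.82%) and 2.81% of SU6656 cells (2.49 to 3.15%). Enterochromaffin-like cells with TPH1 and FEV made up 11.7% and 13.0%, and delta-like cells with SST and HHEX made up 1.42% and 1.85%. Endocrine progenitor-like cells with NEUROG3 made up 5.42% and 5.57%, a difference of 0.15 points whose interval (-0.53 to 0.81) includes 0. Proliferating cells with MKI67 and TOP2A were 166 of the DMSO cells and 158 of the SU6656 cells, -0.52 points (-0.93 to -0.13). An alpha-like class led by GCG was found in both libraries, and its size is not compared because CXCL8, one of its leading genes, differed between the libraries.

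Clusters without a name held 50.8% of DMSO and 57.7% of SU6656 cells. Some were kept out of a class by thresholds set after the data were seen. Among these, cluster 1, with INS and NKX6-1 raised, held 18.4% of DMSO and 20.2% of SU6656 cells. The MALAT1-rich clusters 4, 5 and 13 held 12.8% and 17.3%, at unequal depth per cell. Median UMIs per cell were 7761 in DMSO and 2617 in SU6656 (cluster 4), 6359 and 1982 (cluster 5), and 6229 and 2708.5 (cluster 13). Cluster 8, with keratin genes and markers of duct and of proliferating cells raised, held 2.47% and 3.72%. The sizes of cluster 3, with INS and metallothionein genes raised, and of clusters 9, 10, 14 and 15 are not compared because genes that lead them, such as MT1H, NPY and GHRL, differed between the libraries. Clusters 1, 3 and 7 together, the INS-high clusters, held 34.1% of DMSO and 33.9% of SU6656 cells. Cells with INS as the largest hormone count and at least 10 INS UMIs were 45.1% and 51.4%, at unequal depth per cell. The beta-like difference of -1.54 points was -0.26 when metallothionein genes were left out of the clustering. These differences are not of like sets. The beta-like class held 343 DMSO and 280 SU6656 cells, but 1955 and 2447 without those genes and 702 and 804 at the finer clustering. Its share thus depends on the clustering. The proliferating difference was -0.11 under a stricter cell filter. The enterochromaffin-like difference of 1.25 points was -0.15 at the finer clustering. The delta-like difference of 0.43 points was -0.05 when DMSO clusters were carried to the SU6656 library. The series design text mentions a sort on INS and NKX6-1 reporters, the sample labels name none, and a sort would set these shares.

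**Figure D1:**
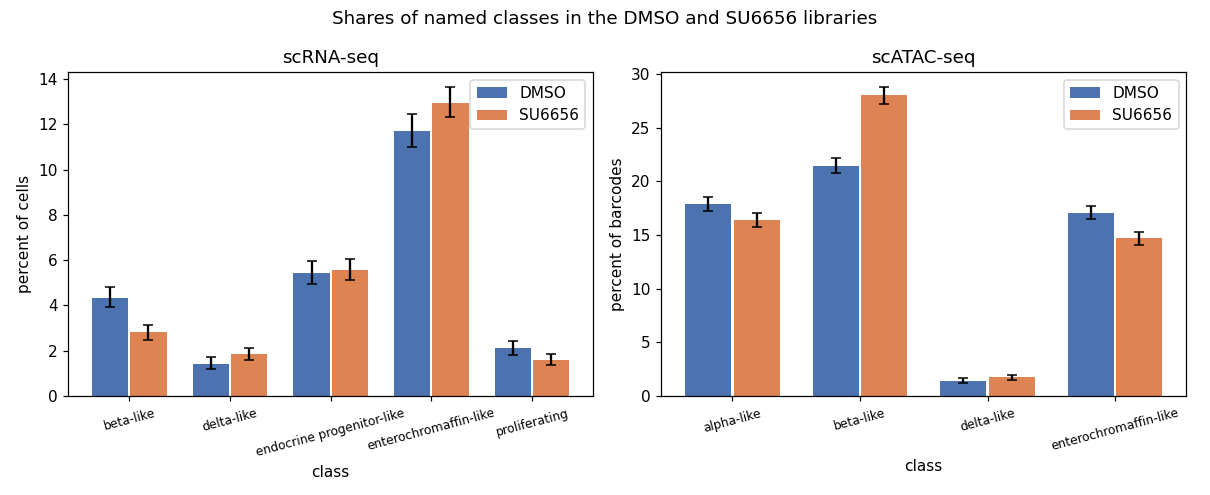
Share of cells (scRNA-seq, left) and barcodes (scATAC-seq, right) in each compared class, in percent, for the DMSO and SU6656 libraries; bars start at 0 and error bars are exact 95% binomial intervals. The beta-like share was 4.35% in DMSO and 2.81% in SU6656 by RNA, and 21.5% and 28.0% by ATAC, where classes were drawn by other measurements and clusters.

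Within the beta-like class (cluster 7, 343 DMSO cells with 2858735 UMIs and 280 SU6656 cells with 1617108 UMIs), INS itself was higher in the SU6656 library, at 26646 against 17451 CPM, a ratio of 1.53 (1.51 to 1.55). Over 19 settings the INS ratio ranged from 1.33 to 1.58, and it was 1.37 in cluster 3, inside 1.5-fold. Among the genes that were most strongly higher, RBFOX1, a splicing regulator of excitable cells, had a ratio of 2.64 (2.22 to 3.14), LYPD1 2.61 (2.05 to 3.32), RNF145, a ubiquitin ligase of sterol control, 2.46 (1.95 to 3.10), and the acid-sensing ion channel gene ASIC2 2.27 (1.82 to 2.83). ERVMER61-1 had a ratio of 2.54, STC1, which encodes the secreted glycoprotein stanniocalcin, 2.25, CALY 2.03 and FAM171A2 2.03. KIZ-AS1 had 2.07, and as an antisense gene it remains uncertain because reads of both strands may be shared.

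PIWIL2, a gene of the small RNA pathway that silences transposons, had the lowest ratio, 0.0120 (0.000302 to 0.0681), from 147 UMIs in DMSO and 1 in SU6656. The lysozyme gene LYZ had 238 and 3 UMIs, a ratio of 0.0223 (0.00456 to 0.0659), but 0.552 in cluster 1 and 0.813 in cluster 3, where few LYZ UMIs were counted. C8orf37-AS1 had 0.0264 and RRN3, an initiation factor of RNA polymerase I, 0.0935, and both are uncertain because an antisense gene and a gene with pseudogenes can share reads. PIWIL2, C8orf37-AS1 and RRN3 were lower in each of the 8 largest clusters alike, not in beta-like cells alone. Lower ratios were also found for UCN, the gene of the peptide urocortin (0.246), COL6A6 (0.310), HOPX (0.341), PARVB (0.346), MPPED2 (0.351), the leptin receptor gene LEPR (0.354), ACSM3 (0.359) and ST8SIA4 (0.381).

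Of 9265 genes measured with at least 50 UMIs in these cells, 305 were higher and 448 lower (40.5% of calls higher), and scaling by the median ratio of genes gave 375 higher and 347 lower (51.9%). Several of these genes turned in other sets of INS-expressing or endocrine cells: ERVMER61-1 was below 1 in 5 such sets (0.777 in cluster 3), LYPD1 had a ratio of 0.589 in cluster 1, STC1 0.796 and HOPX 1.01 in cluster 3, LEPR 1.201 in cluster 3, and RBFOX1 0.903 in cells with INS as the largest hormone count. Over 19 settings others kept their side but reached values inside 1.5-fold: UCN and COL6A6 0.736, PARVB 0.757, ST8SIA4 0.817 and ASIC2 1.13.

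Genes of cholesterol and fatty acid synthesis were the group with the lowest median in beta-like cells. Of 26 measured, 6 were lower and 0 higher, and the median log2 ratio of -0.38 lay at percentile 0 of 10000 random lists of like expression. STARD4, a sterol carrier, had a ratio of 0.505 (0.368 to 0.683), MSMO1 0.566 (0.500 to 0.639), DHCR7 0.614 and HMGCS1, an early enzyme of the mevalonate pathway, 0.621. The median of this list was below that of all genes in each of 19 settings, by -0.36 to -0.16.

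The respiratory chain genes of the mitochondrial genome had a median log2 ratio of -0.35 (percentile 0.010), although 0 of 13 passed the rule. MT-ND1 had 0.670 (0.581 to 0.771), MT-ATP6 0.674 and MT-CO3 0.704, and nuclear copies of these genes may share their reads. Relative to all genes this median was 0.06 in cluster 3 alone, against -0.28 in beta-like cells. Nuclear encoded respiratory chain genes had a median of -0.03 (percentile 87.7), with 0 of 40 past the rule. Targets of ATF4 and CHOP, which answer amino acid shortage and unfolded protein, had a median of -0.24 (percentile 1.80). Of 19 measured, 3 were lower: PSAT1 (0.446), CHAC1 (0.510) and the asparagine synthetase gene ASNS (0.538). PSAT1 turned to 1.38 when cells were thinned to 1 depth. Chaperones of the endoplasmic reticulum had a median of -0.22 (percentile 0.360) with 1 of 25 lower, SEL1L at 0.651. That list lay above all genes, by 0.06, in the pooled INS-high clusters, and in cluster 1 it was at percentile 99.8.

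Genes of zinc handling moved both ways in beta-like cells. Of 17 zinc transporters measured, 2 were higher, SLC39A13 (1.60, 1.05 to 2.42) and SLC39A1 (1.57, 1.12 to 2.19). The 2 lower were SLC30A6 (0.469, 0.233 to 0.878) and SLC30A7 (0.615, 0.433 to 0.860), which load zinc into the secretory pathway. The list's median was -0.08 (percentile 44.3). SLC30A8, the zinc transporter of insulin granules, had 0.948 (0.853 to 1.05), SLC39A14 0.972 (0.718 to 1.31), and SLC30A1, the plasma membrane exporter, 0.760 (0.586 to 0.979). SLC39A13 had 0.838 in cluster 3, and SLC39A1 had 1.14 when each cell weighed the same. Over 19 settings SLC39A1 reached 1.01, SLC30A6 0.895 and SLC30A7 0.812, inside 1.5-fold.

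Metallothioneins, the small proteins that bind zinc, had a median of -0.21 at percentile 6.74, inside the range of random lists. Of 9 measured, 3 were lower and 0 higher: MT1H (0.429, 0.232 to 0.748), MT1M (0.511) and MT1B (0.601), while MT1F had 0.765, MT1X 0.917 (0.850 to 0.989) and MT2A 0.929 (0.865 to 0.998). These paralogs are near-identical and each value is uncertain. The list's direction in beta-like cells did not hold in every setting. Relative to all genes the median was -0.14 at full depth and 0.08 in thinned cells, where MT1B had 1.52 and MT1M 1.04. Over 19 settings this median ranged from -0.55 to 0.08. Thinned cells hold fewer counts, so the thinned value cannot tell an effect of depth from counting error. Other sets of INS-expressing cells differed. Cells with INS as the largest hormone count had a median of -0.49 (percentile 0) with 3 of 9 lower. The list was also below the random range in cluster 3 and in the pooled INS-high clusters, but inside it in cluster 1 and in clusters 1 and 7 together.

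Hypoxia genes, the targets of the oxygen-sensing factor HIF, had a median of -0.08 (percentile 48.9) over 27 measured, with INSIG2 lower (0.582) and 0 higher. In cluster 1, which also expresses INS, the list had 0.11 (percentile 99.97) with 5 of 32 higher and 2 lower, and in clusters 1 and 7 together 0.03 (percentile 98.8), so the result depends on the set of INS-expressing cells. HIF1A had a ratio of 0.884 (0.731 to 1.07). VEGFA, the main vessel growth factor, had 1.03 (0.897 to 1.18). Of 5 pro-angiogenic factors measured none passed the rule, and their median was 0.14 (percentile 89.0), with ANGPT2 at 1.36 (1.02 to 1.80). Glycolysis enzymes had a median of 0.03 (percentile 93.7) with 1 of 16 higher, the neuronal enolase ENO2 (1.51).

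Of 39 beta cell hormone, granule and identity genes, 2 were higher, INS and the incretin receptor gene GIPR (1.77, from 39 UMIs in each library), and 1 was lower, IAPP, which encodes amylin (0.565, 0.496 to 0.642). The list's median was -0.003 (percentile 94.6), and NKX6-1, a factor of beta cell identity, had 1.14 (1.04 to 1.26). The list lay at percentile 98.7 in INS-high clusters drawn without metallothionein genes. It lay at 82.0 in cells with INS as the largest hormone count, so its place depends on the set of cells. GIPR had 0.994 in thinned cells, and IAPP had 0.960 when each cell weighed the same and turned to 1.41 (1.13 to 1.77) in cluster 3. GCG had 0.475 and SST 0.531 in beta-like cells, and GCG turned to 1.27 in cluster 1. MAFA with 21 and 16 UMIs and SRC with 37 and 12 UMIs were under the minimum count, so no call was made.

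Src family kinases and partners had a median of -0.15 over 7 genes (percentile 29.6), and YAP and SRF targets 0.01 over 9 (percentile 76.9), with 0 past the rule in either list. Immediate early genes had -0.02 over 12 (percentile 66.2) with FOS lower (0.538), but in cluster 3 the list had 0.41 (percentile 100) with 3 of 13 higher and FOS at 1.34, and in cells with INS as the largest hormone count 0.09 (percentile 99.5). Cytosolic heat shock genes had 0.03 over 13 (percentile 87.8), with BAG3 at 1.87 and HSPH1 at 0.659, and BAG3 turned to 0.710 in thinned cells. Targets of p53 and apoptosis genes had -0.14 over 11 (percentile 29.0) and oxidative stress genes -0.01 over 14 (percentile 77.8). TXNIP, an inhibitor of thioredoxin that belongs to both of these lists, was higher at 25.4 against 10.1 CPM (ratio interval 1.52 to 4.17), and the glutathione peroxidase gene GPX2 was higher at 2.17 (1.43 to 3.31). Extracellular matrix genes had -0.05 over 9 (percentile 57.7) with COL4A2 lower (0.542). Of the mitosis list 2 genes were measured, CDKN1A at 0.578 (0.313 to 1.02) and PCNA at 1.04, too few for a median. Over 19 settings the ratios of several lower genes came inside 1.5-fold: INSIG2 reached 0.934, DHCR7 0.903, ASNS 0.888, COL4A2 0.885, CHAC1 0.865, HSPH1 0.860 and SEL1L 0.816.

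**Figure D2:**
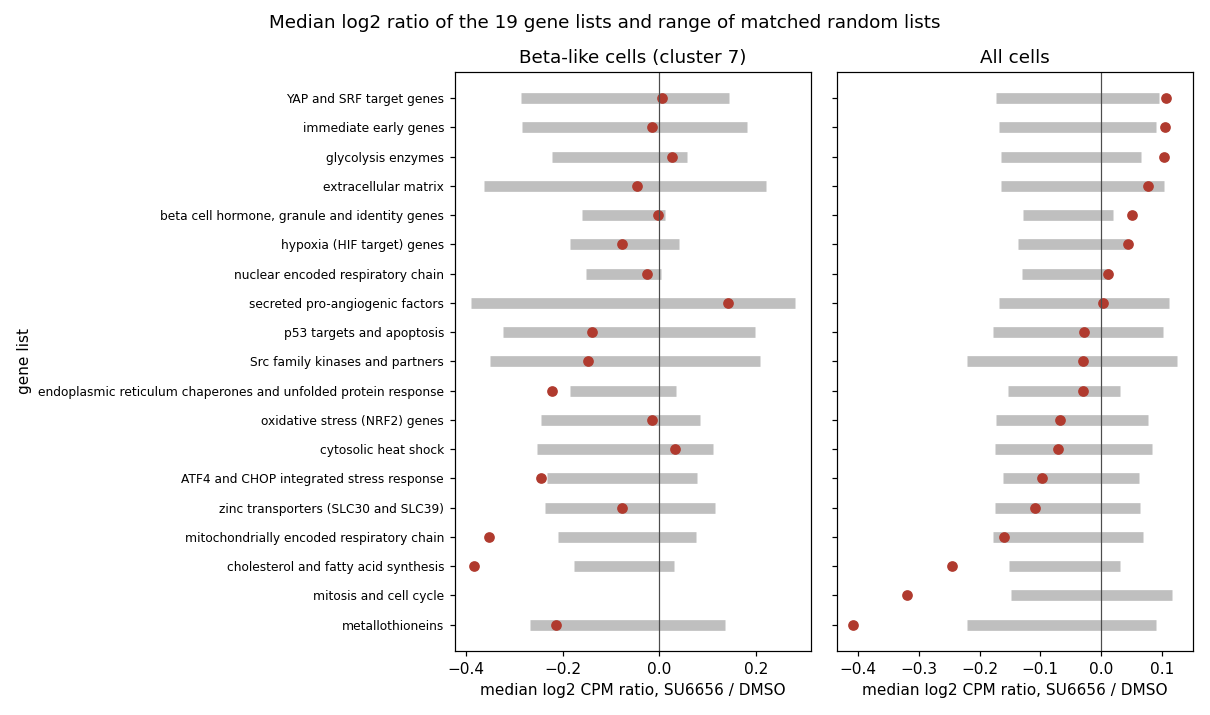
Median log2 ratio of CPM, SU6656 over DMSO, of each gene list (points) in beta-like cells (left) and all cells (right); grey bars span the central 95% of 10000 random lists of like size and expression, and the mitosis list has no point on the left because 2 members were measured. Cholesterol and fatty acid synthesis lies below its bar in both panels (-0.38 and -0.25). Of the panels, metallothioneins lie below their bar on the right only (-0.41). Their direction in beta-like cells was lost in thinned cells, which hold fewer counts.

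Over all cells, which mix every cluster, zinc-responsive genes were lower in the SU6656 library. SLC30A1, whose transcription follows cell zinc, had 77.4 against 121 CPM, a ratio of 0.638 (0.613 to 0.663). Metallothioneins had a median of -0.41 (percentile 0), with MT1H (0.496, 0.465 to 0.530) and MT1B (0.630, 0.606 to 0.654) lower, MT1X at 0.723 and 0 of 9 higher. Relative to all genes that median lay between -0.57 and -0.34 in 12 settings. In the 8 largest clusters SLC30A1 ranged from 0.423 to 0.760, whereas MT1X was above 1 in the endocrine progenitor-like cluster (1.15, 1.03 to 1.29).

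**Figure D3:**
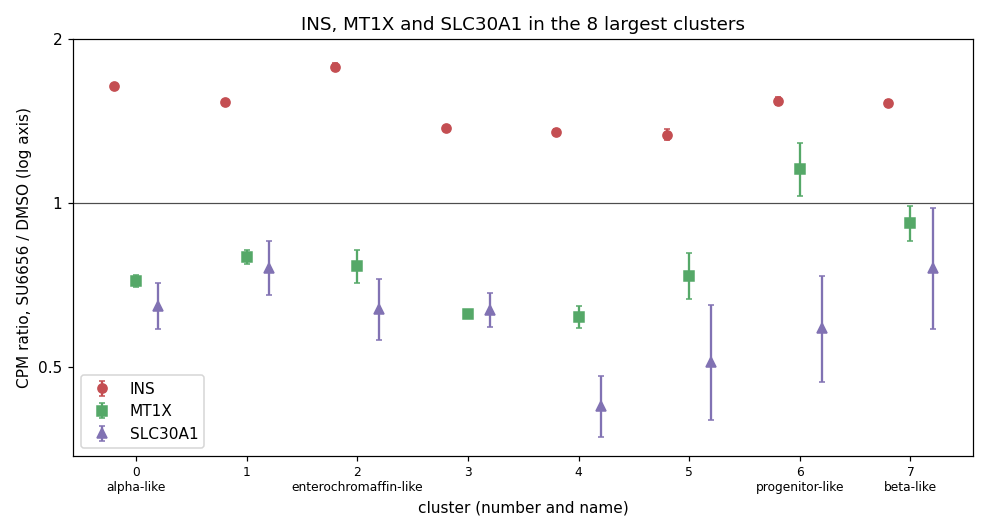
Ratio of CPM, SU6656 over DMSO (log axis), of INS, MT1X and SLC30A1 in the 8 largest clusters by number and name; error bars are 95% counting intervals and the line marks a ratio of 1. INS lies above 1 and SLC30A1 below 1 in all 8, and MT1X lies below 1 in 7 and above 1 (1.15) in the progenitor-like cluster.

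Mitosis genes were lower as a group over all cells, with a median of -0.32 (percentile 0) and 4 of 29 lower: CENPE (0.571), the cell cycle inhibitor gene CDKN1A (0.605), KIF11 (0.636) and KIF20A (0.643). Within the proliferating class the list had -0.38 (percentile 0.010) with 5 of 29 lower, and in the INS-high clusters -0.43 (percentile 0.330). Cells chosen by INS as the largest hormone count had 0.13 (percentile 98.6), and KIF11 reached 0.939 over 12 settings. Cholesterol genes had a median of -0.25 (percentile 0.020), with STARD4 (0.586), SQLE (0.646) and MSMO1 (0.659) lower.

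Targets of YAP and SRF, which respond to cell shape and tension, had a median of 0.11 (percentile 98.3) and 5 of 22 were higher, among them ANKRD1 (6.93, 5.73 to 8.43), CCN2 (4.87, 3.25 to 7.51), CCN1 (1.75) and AMOTL2 (1.70). With each cluster given the same weight in both libraries the list was inside the random range (percentile 95.2) with 2 of 22 higher. CCN1 then had 1.197 and AMOTL2 1.29. Of the ANKRD1 UMIs in the SU6656 library, 715 of 753 came from cluster 8, the keratin-rich cluster that was 2.47% of DMSO and 3.72% of SU6656 cells. Glycolysis enzymes had a median of 0.10 (percentile 99.6) with SLC16A3 higher (1.52). Hypoxia genes had 0.04 (percentile 97.7) with PFKFB3 higher (1.58). Immediate early genes had 0.11 (percentile 98.5) with IER2 (1.72) and FOSB (1.81) higher and KLF4 (0.502) and DUSP6 (0.647) lower. Beta cell genes had 0.05 (percentile 99.6) with INS (1.56, 1.55 to 1.56) and DLK1 (1.53) higher, and ADCYAP1 (0.569) and IAPP (0.652) lower. With each cluster given the same weight in both libraries INS had 1.49, DLK1 1.13 and IAPP 0.747, inside 1.5-fold.

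Among pro-angiogenic factors over all cells, VEGFA had 1.01, the chemokine gene CXCL8 0.221 (0.194 to 0.251), FGF2 0.373 (0.219 to 0.609), TYMP 2.09 (1.73 to 2.54), and 3 of 24 were higher and 3 lower. HMOX1, the heme oxygenase gene, had 2.16 (1.81 to 2.58). Of 19304 genes measured, 629 were higher and 769 lower, a split that turns under other settings. The median ratio of genes gave 717 higher and 655 lower, and leaving out the MALAT1-rich clusters 643 and 626. Giving each cluster the same weight in both libraries gave 771 and 545, and thinned cells 496 and 411. The mean over cells of each cell's CPM gave 1504 and 808. With that mean of each cell's CPM, glycolysis enzymes no longer lay above all genes (-0.00015). In pooled counts 8 lists lay outside the range of random lists and the others inside, against 3 outside with that mean and 3 in thinned cells.

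In scATAC-seq the authors' peak lists held 253500 DMSO and 243232 SU6656 peaks, covering 217657259 and 208302426 bp at a mean of 972 and 946 counts per kb. Of the DMSO peaks 86.7% overlapped a SU6656 peak, and of the SU6656 peaks 90.3% overlapped a DMSO peak. Among 218730 regions called in both libraries with at least 100 counts, 3202 (1.46%) were more accessible in SU6656 and 1831 (0.837%) less. The same rule called 1.06% of simulated peaks that held no difference, from counting error alone. Scaling by the median ratio gave 2771 and 2170, and among regions with at least 500 counts fewer were higher (388) than lower (445). Within ATAC classes the calls were 3004 higher and 2768 lower of 151404 regions in beta-like and 2181 and 2138 of 107261 in alpha-like barcodes. They were 1834 and 1777 of 106471 in enterochromaffin-like and 234 and 299 of 14947 in delta-like barcodes. Calls without a difference were not simulated at the depth of these classes. Regions within 1 kb of a gene end were called higher in 0.892% and lower in 0.458%, and regions between genes in 1.63% and 0.984%. These locations were not matched on counts per region, on which calls from counting error depend, so their shares cannot be compared.

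Gene-end regions, within 1 kb of either annotated end of a gene on GRCh38, were compared by gene. Among protein-coding genes with at least 500 counts FLT4, a receptor for vascular endothelial growth factor C, had the largest ratio, 2.49 (2.03 to 3.09), at a region inside the gene next to its end (chromosome 5, 180648836 to 180649901) with 265 and 618 counts. SPIRE2, an actin nucleator gene, had 32.4 against 15.4 CPM (ratio interval 1.98 to 2.23) at a region across the gene's end (chromosome 16, 89827558 to 89829013). ZFP3 had 1.88, ZNF335 1.80 and the chromatin remodeller gene CHD5 1.80. GDNF, a neurotrophic factor gene, had the smallest ratio, 0.498 (0.432 to 0.574), across its end (chromosome 5, 37839791 to 37840625). The potassium channel gene KCNJ12 had 0.553 at its region. C1QL3 (0.533), CEP170B (0.579) and TAFA5 (0.584) were sums of several regions of which 1 each was lower, at 0.463, 0.549 and 0.433, while the others had 1.01 and 0.956, 1.19 and 1.12.

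Among 14 genes always named, none passed the rule at its gene ends. SLC30A1 had 0.966 (0.937 to 0.995), SLC30A8 1.06, SLC39A14 0.994, MT1X 1.01, MT2A 0.962, VEGFA 1.06, HIF1A 0.991, INS 1.18, NKX6-1 1.06, MAFA 1.01, SRC 1.05, SST 1.18, GCG 0.799 (0.695 to 0.913) and IAPP 1.48 (1.00 to 2.22), the last from 93 and 129 counts. Metallothionein gene ends had a median log2 ratio of -0.07 (percentile 0.370), mitosis genes -0.02 (0.920), oxidative stress genes -0.02 (1.17) and nuclear encoded respiratory chain genes 0.04 (98.9). The other lists lay inside the range of random lists, and a single list member, of the extracellular matrix list, passed the rule.

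Beta-like barcodes by ATAC, with INS and IAPP accessibility raised, were 21.5% (20.8 to 22.2%) in DMSO and 28.0% (27.2 to 28.8%) in SU6656. Alpha-like barcodes were 17.9% and 16.4%, enterochromaffin-like barcodes 17.1% and 14.7%, delta-like barcodes 1.42% and 1.74%, and unnamed clusters held 42.1% and 39.2%. At the finer clustering enterochromaffin-like barcodes were 7.05% and 7.07%, and alpha-like barcodes 16.5% and 13.8%. These classes rest on gene-body accessibility of other cells than the RNA classes, so the shares of the assays are not of the same population. Across 14276 genes, which are not independent replicates, the RNA ratio over all cells and the gene-end accessibility ratio had a Spearman rank correlation of 0.144.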

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

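Settings on the choice of INS-expressing cells, the highest doublet scores and clustering without metallothionein genes were chosen after the results were seen, and the cause of a difference was not tested unless stated. Of 159 counts and shares 113 held and 44 moved, of 528 list medians 419 held, of 2939 gene ratios 2409 held, and of 72 ATAC list medians all 72 held. Keeping doublets equals the values reported, since 0 cells were marked, and the motif search in whole regions was not run.

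In beta-like cells, 305 genes were higher and 448 lower. Stricter rules gave 55 and 116 at 2-fold and 57 and 127 at 200 UMIs or more by construction, and thinned cells gave 92 and 171. At 10 UMIs or more 478 were higher. The mean of each cell's CPM gave 489 and 707, all endocrine clusters 591 and 715, cells with INS as the largest hormone 893 lower and Leiden 1.0 683 lower. Lists outside the random range numbered 4, against 7 in clusters 1 and 7, 8 in cluster 1, 7 in all endocrine clusters and 8 with INS as the largest hormone. Over all cells the mean of each cell's CPM gave 1504 higher and 3 lists outside in place of 8. The 2-fold rule gave 148 and 180, 200 UMIs or more 269 and 368, and thinning 411 lower and 3 lists.

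Reversed under thinning were BAG3 (0.710), GIPR (0.994), MT1B (1.52), MT1M (1.04) and PSAT1 (1.38) in beta-like cells and SPARC (0.730) over all cells. Thinned ratios rest on fewer counts and are given without an interval. For genes with few UMIs a reversal under thinning thus cannot be told from counting error. The chaperone list, below all genes in cluster 7, lay above them in the INS-high pool (0.0599), clusters 1 and 7 (0.0502), cluster 1 (0.144), cluster 3 (0.0767), all endocrine clusters (0.00817), cells with INS as the largest hormone (0.0881) and clustering without metallothioneins (0.0539). The mitochondrial list reversed in cluster 3 (0.0577), and glycolysis over all cells with each cell's mean CPM (-0.00015). In the INS-high pool ERVMER61-1 (0.968), FOS (1.05), GCG (1.14) and SLC39A13 (0.998) reversed. In clusters 1 and 7 BAG3 (0.967) and GCG (1.01) did. Cluster 1 reversed BAG3 (0.797), ERVMER61-1 (0.987), FOS (1.02), GCG (1.27), LEPR (1.099), LYPD1 (0.589) and MT1M (1.16). Cluster 3 reversed ERVMER61-1 (0.777), FOS (1.34), GCG (1.34), HOPX (1.01), IAPP (1.41), LEPR (1.201), SLC39A13 (0.838) and STC1 (0.796). All endocrine clusters reversed ERVMER61-1 (0.973), FOS (1.05) and SST (1.16). Cells with INS as the largest hormone reversed ERVMER61-1 (0.921), FOS (1.07), GCG (1.25) and RBFOX1 (0.903). Leiden 1.0 reversed GCG (1.1001) and MT1M (1.05), the stricter filter MT1B (1.01), leaving out the highest doublet scores GCG (1.07), and clustering without metallothioneins MT1M (1.08).

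The beta-like share differed by -1.54 points, -0.84 at Leiden 1.0 and -0.26 with metallothioneins left out of clustering, where 2 clusters were beta-like. The class held 343 DMSO and 280 SU6656 cells as reported, 702 and 804 at Leiden 1.0, and 1955 and 2447 without metallothioneins. These differences are thus not of like sets. The enterochromaffin-like difference was -0.15 at Leiden 1.0, the delta-like one -0.0469 with carried clusters, and the proliferating one -0.11 with the stricter filter. By ATAC, 86.2% and 89.9% of peaks overlapped over at least 0.5 of both. At 500 counts or more 388 regions were higher and 445 lower, a count whose order differs from the 3202 and 1831 reported, and 256 and 168 at 2-fold. The Spearman rank correlation of RNA and accessibility ratios across genes was 0.174 over the gene body. Alpha-like shares were 16.5% and 13.8% and enterochromaffin-like ones 7.05% and 7.07% at Leiden 1.0, and at 3000 counts or more the alpha-like share in SU6656 was 15.2% and beta-like shares were 19.7% and 27.0%.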

Other observations

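The tests below were chosen after the results were seen, except that of UMIs moved between neighbouring genes, for all 12 genes. Outside the beta-like class, the hypoxia and glycolysis lists lay above the random range in enterochromaffin-like cells. Most hypoxia genes passed the rule in neither direction. Of 35 hypoxia genes 7 were higher and 0 lower, with a median log2 ratio of 0.20 at the 100th percentile of random lists. STC2 had a ratio of 3.18 (2.46 to 4.14), NDRG1 2.44 (2.21 to 2.70) and LDHA 1.85 (1.71 to 2.01). Among glycolysis enzymes SLC16A3, a lactate exporter, had 3.95 (2.77 to 5.75). These lists were also above the random range in alpha-like cells (hypoxia at percentile 99.8 with 4 of 36 higher, glycolysis at 99.7) and in cluster 8 (98.2 and 99.7). In enterochromaffin-like cells 8 of 27 cholesterol genes were lower.

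In the keratin-rich cluster 8, left without a name because 3 low-quality markers were raised, YAP and SRF targets had a median of 0.44 at the 100th percentile and 7 of 18 were higher, ANKRD1 at 4.42 (3.65 to 5.38), CCN2 at 4.66 and TAGLN at 6.37. Immediate early genes were higher in 6 of 9, with EGR1 at 2.03 and JUN at 1.90. All 8 metallothioneins measured there were lower, MT1H at 0.142 (0.0847 to 0.227). Beta cell genes were higher there (0.53, 11 of 30) and mitosis genes lower (-0.38, 8 of 21). Of all 8651 genes measured in cluster 8, 621 were higher and 424 lower. The cluster had 9 proliferating markers raised beside 11 of duct, and its mix of cells was not compared between the libraries. Metallothioneins went the other way in delta-like cells, with MT1G at 2.55 (2.12 to 3.09), MT1E at 1.85 and MT2A at 1.69. The list's median of 0.75 lay at percentile 99.99. MALAT1, a nuclear RNA, had 0.337 (0.319 to 0.356) in the same delta-like cells. In endocrine progenitor-like cells the metallothionein median was 0.28 (percentile 99.7). These differences between clusters were not tested.

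The first pattern is a set of 12 genes that moved 3-fold or more alike in each of the 8 largest clusters: over all cells 4 were higher, among them TERB1 (131, 89.2 to 201) and HES4 (10.0, 8.20 to 12.4), and 8 lower, among them UTF1 (0.00517), PIWIL2 (0.00812), C8orf37-AS1 (0.0200), RRN3 (0.0703) and RPGRIP1 (0.0730). Accessibility argued against a change at the measured gene ends of 4 genes, since 0 of 4 moved to that side by 1.5-fold. Only regions called in both libraries were measured, so a gene end open in 1 library alone could not be seen. PIWIL2, RPGRIP1 and TERB1 were among the genes without a measured region. UMIs moved between neighbouring genes were argued against for the 4 genes with a neighbour within 5 kb (UTF1, RRN3, RPGRIP1 and TERB1), whose neighbours moved the other way by at most 22.5% of the UMIs. For the other 8 it cannot be told apart from a change of the genes: 0 had a partner, but 4 had no place and 4 no neighbour in the gene table used here, which holds 66.5% of the RNA symbols. Genes that differ in every cluster could also mark a difference between the cell batches or library runs, which 1 library per group does not separate from SU6656.

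The next pattern is the INS ratio above 1 in the INS-high clusters, which pooled had a log2 ratio of 0.50, inside 1.5-fold. The INS ratio was above 1 in 16 of 16 clusters. Free INS RNA in droplets would add alike to all clusters, but the gain in the INS-high clusters (8065 CPM) was 9.65 times that in cluster 8 (836 CPM), so it is not the whole cause. The gain was not particular to INS-high clusters: it was 503 CPM in cluster 10, 3599 in enterochromaffin-like, 5434 in alpha-like, 5891 in progenitor-like and 7414 in delta-like cells and 8663 in cluster 14. The log2 ratio was 0.53 in thinned cells and 0.50 at full depth. Thinning leaves the expected share of INS in each cell unchanged, so these values cannot decide on lower depth per cell. A hypothesis that these cells carry more INS RNA after SU6656 was not tested. Part of the gain in clusters without beta markers could be free RNA. Lower depth per cell and a difference between cultures stay open.

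Lower metallothioneins and SLC30A1 over all cells form another pattern. A smaller share of metallothionein-rich cells argued poorly. The list's median relative to all genes was -0.45 with each cluster given the same weight in both libraries and -0.37 as pooled. A uniformly lower response of zinc-responsive genes was not found either, since MT1X reached 1.15 in the endocrine progenitor-like cluster, although both genes were below 1 in 7 of 8 clusters and SLC30A1 in 8 of 8. In the beta-like cluster the list turned to 0.08 in thinned cells, which hold fewer counts. A difference between the cultures stays open, and no biological explanation was tested.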
